A study of Mus musculus and Homo sapiens with 16 samples.

How the data were processed

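RNA-seq was done on 16 samples in 8 groups of 2, from mouse hematopoietic stem cells, mouse J1 embryonic stem cells, human H9 embryonic stem cells and human CD34 stem and progenitor cells, each with and without DNMT3A. The groups were taken from the sample titles. RNA came from a PicoPure kit for the blood cells and a Qiagen kit for the embryonic stem cells, per the labels' protocols. The series text and the sample labels name different library kits, a stranded TruSeq mRNA kit in the former and a SMARTER mRNA-Seq kit in the latter, so it is open whether the libraries keep strand. Without strand, intron reads cannot be told from those of a gene on the opposite strand. Whether the 2 samples of a group came from separate cultures, animals or donors is not given in the sources used here.

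The authors deposited 1 table per cell system, with 1 row per intron. Its values are a ratio, the intron retention score, in which the authors divided the RPKM-normalized read density inside the intron by that of reads spanning the junction, per the labels. The authors then averaged the score over the samples of each group, per the labels and the file headers. Reads were aligned with HISAT2 and handled with SAMtools, on mm10 and hg38, per the submitters' processing notes; versions and settings are not given in the sources used here. Each gene is represented by 1 RefSeq transcript. Which introns the authors kept is not given either, and the tables differ in this, with 48007, 39277, 82402 and 74398 introns read for mouse HSC, mouse ESC, human ESC and human CD34 cells. Because RPKM normalization divides by length and a score is a ratio of densities, a short or weakly expressed intron rests on few reads, and its score can be 0 or large by counting alone. The depth per sample is unknown, so no interval or floor was computed for a score, and an average listed at 0 is reported as that.

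The listed positions are the flanking exon bases, so the intron was taken as the bases between them. For mouse ESC, 39265 introns (99.97%) matched introns of the GENCODE vM21 annotation on mm10, and intron numbers, coding or UTR position and coordinates are given from that match. For mouse HSC, 1146 introns (2.39%) matched, so its positions are on another build and are not printed, apart from intron numbers found by transcript and intron length. The human tables hold positions up to 59081711 on chromosome 19 and 51220616 on chromosome 22, which lie past the ends of those chromosomes in hg38, so no human coordinates are printed. Introns of the Y chromosome were left out of the human tables. The plan matched introns between tables of a species by position; for mouse this was replaced by transcript and intron length, using introns unique on both.

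Within each table, introns with a mean score of at least 0.01 over both groups were kept, and the change was log2 of (score + 0.01) without DNMT3A over (score + 0.01) in the control. An intron was higher or lower when the change was at least 2-fold on that scale and the scores differed by at least 0.05. This rule of size, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. With group averages there is no test across samples, no leave-out of a sample and no pairing.

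A gene's change was the mean over its kept introns. The 22 gene lists were DNA methylation machinery, U2 snRNP and branch point factors, SR proteins, hnRNP proteins, other spliceosome subunits, splicing factor kinases, minor spliceosome subunits, nonsense-mediated decay factors, pluripotency factors, retinoic acid response, germ layer regulators, blood stem cell regulators, erythroid and megakaryocytic markers, myeloid markers, lymphoid markers, stromal and feeder cell markers, DNA damage response and repair, chromatin modifiers, p53 pathway, cell cycle regulators, cytosolic ribosomal proteins and respiratory chain subunits. The median of each list with at least 5 measured genes was placed among 10000 random lists of the same size, matched on mean score (10 classes of equal size) and on the number of kept introns, as a description of these libraries. Overlaps between comparisons were set beside the number that independent lists would share, in all and within classes of mean score (introns) or number of kept introns (genes). Intron length was not matched. The ribosomal protein and respiratory chain lists were taken by symbol prefix. The latter therefore also holds genes that are not subunits, such as the assembly factor gene NDUFAF5.

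Named genes were, per comparison, the 10 introns with the largest positive and the 10 with the largest negative change among those past the rule, with a score of at most 1 in both groups and a mean of at least 0.05, 1 per gene; up to 3 members of each list by the same ranking; DNMT3A; and up to 10 genes per direction past the rule the same way in at least 3 of the 4 comparisons. Symbols that are provisional, antisense or pseudogene names were passed over. The text leaves out some for length.

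Alternatives were a pseudocount of 0.001 or 0.05, no filter or a minimum mean of 0.05, a fold limit of 1.5, a difference limit of 0.02 or 0.1, leaving out scores above 1 or scores of exactly 0, centring on the median change, 1 intron per gene, the gene's highest-score intron in place of its mean for lists, and a level of 0.05 in place of 0.1 for baseline retention. Centring moved the log2 change only, and the difference limit stayed on the scores as listed, so a common shift was not fully removed. Introns of at least 1000 bases and a length-weighted score per gene were added after seeing the data.

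The code was tested on simulated data made from each control column, with 200 introns changed and the rest given random noise. Among introns starting at 0.1 or more, 4-fold and 10-fold decreases were all called, and 3-fold increases were called for 100%, 98%, 100% and 100% of 50 introns in mouse HSC (29827 introns), mouse ESC (21690), human ESC (23019) and human CD34 cells (31474). Among introns starting at 0.05 or more, 4-fold decreases were called for 76%, 64%, 82% and 74%, since many cannot differ by 0.05. Changes of 1.5-fold were called in 0% to 4%, and 0% of unchanged introns were called. The noise was small beside the 2-fold limit and made no new zeros. That 0% is therefore not a rate of false calls under counting noise. Of 100 random lists per comparison, 3%, 6%, 8% and 2% fell outside the central 95%. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.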

Results

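RNA-seq libraries were compared with and without the DNA methyltransferase DNMT3A in 4 stem cell systems, and the quantity reported for each intron was an intron retention score, the density of reads inside the intron relative to the density of reads spanning its splice junction. A score of 0 means that no intron reads were listed, and a score near 1 means that the intron was read about as densely as the spliced junction. The 16 samples formed 8 groups of 2. They were mouse hematopoietic stem cells (HSC), wild type or Dnmt3a knockout; mouse embryonic stem cells (ESC) of the J1 line, wild type or Dnmt3a knockout, after 24 h of all-trans retinoic acid (ATRA), a differentiation signal; human ESC of the H9 line, wild type or with DNMT3A degraded, after 12 h of ATRA; and human CD34 stem and progenitor cells that received Cas9 alone or Cas9 with a guide against DNMT3A (sgDNMT3A). The H9 group with DNMT3A degraded is labelled dTAG-13, a small molecule that sends tagged proteins to degradation. The series title names the question as how DNMT3A bears on splicing when stem cells leave the stem state.

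The values are the authors' group averages, so no spread between samples, no test and no p-value could be had, and the read depth behind a score is unknown. Every difference below is therefore a difference between averages of 2 samples, without a replicate check. An intron was called higher or lower when its score differed by at least 2-fold, on the log2(score + 0.01) scale, and by at least 0.05. This scale understates the change of low scores, and where a group was listed at 0 no fold is given. A gene counts as higher or lower when at least 1 of its introns did, so a gene can count in both directions. A gene with more kept introns also has more chances to count.

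Baseline retention differed between the systems. The median score was 0.0180 in wild-type mouse HSC, 0.0123 in wild-type mouse ESC, 0.00649 in Cas9-treated human CD34 cells and 0.00262 in wild-type human ESC. Introns with a score of at least 0.1 made up 14.7%, 8.63%, 7.88% and 3.97% of the listed introns in these groups. Without DNMT3A the same shares were 26.9%, 9.28%, 12.3% and 4.32%, and in mouse ESC the direction turned at a level of 0.05, with 18.1% in wild type and 16.5% in the knockout. The tables were made separately, so levels set across them also differ in which introns were listed.

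**Figure D1:**
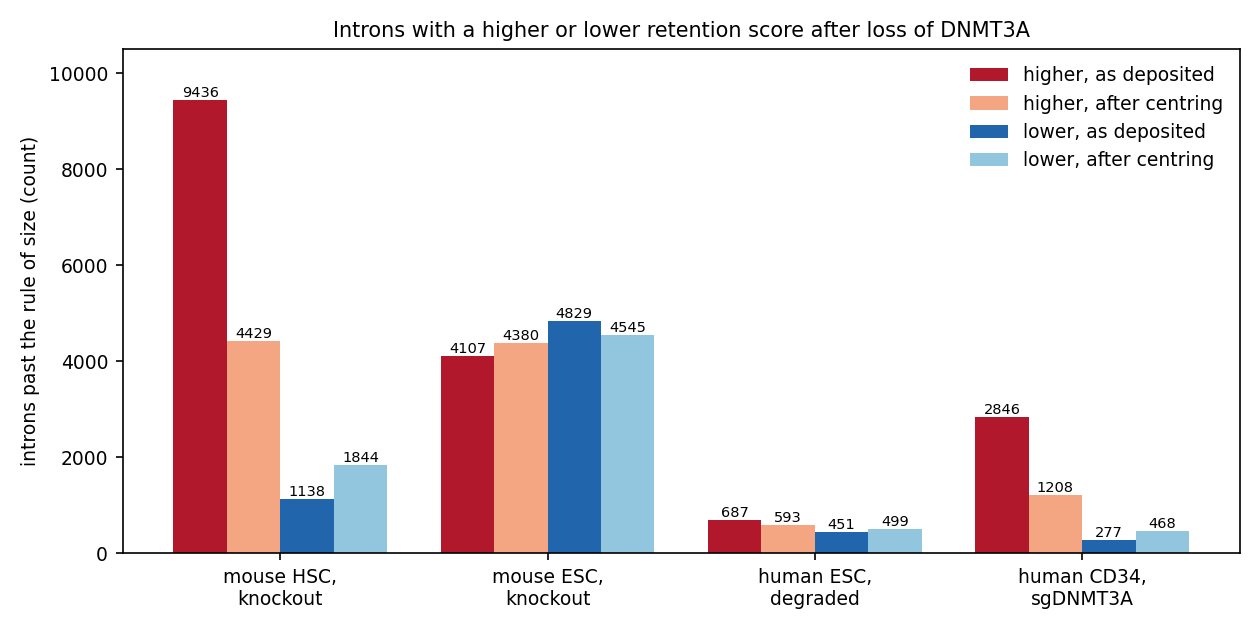
Number of introns (vertical axis, count) past the rule of size in each comparison (horizontal axis), higher in red and lower in blue, from the scores as deposited (dark bars) and after centring each comparison on its median log2 change (light bars). Higher introns outnumber lower ones 9436 to 1138 in mouse HSC and 2846 to 277 in human CD34 cells, and centring leaves 4429 to 1844 and 1208 to 468. Centring moves the log2 change but not the difference in score that the rule asks for.

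In mouse HSC, knockout of Dnmt3a went with higher scores across the transcriptome. Of 35773 introns kept, 9436 were higher, 1138 lower and 25199 neither, and the median log2 change was 0.81. Among the SR proteins, which bind exonic enhancers and recruit the spliceosome, 9 of 12 genes were higher and 0 lower, with Tra2b going from 0.116 to 0.557 (log2 change 2.17), Srsf7 from 0.256 to 0.823 (1.65) and Srsf11 from 0.0304 to 0.164 (2.11). Cytosolic ribosomal protein genes lay below other genes, at a median of 0.26 against 0.75 for all genes. Centring on the median took the split to 4429 higher and 1844 lower, or 70.6% higher instead of 89.2%.

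The targeted gene was listed with 2 introns in this table. Intron 22 of 22 of Dnmt3a, 722 bases within the coding region, had a score of 0.0348 in wild type and 0.209 in the knockout. Intron 10, of 255 bases, was listed at 0 in wild type and at 0.0526 in the knockout. A retention score does not measure the amount of the transcript or the protein, so neither value checks the genotype.

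The introns with the largest changes were short and listed at 0 in 1 of the groups. Higher in the knockout were introns of Wee1, the kinase that holds cells before mitosis (0 to 0.948), Wdr5, a shared subunit of histone H3K4 methyltransferase complexes (0 to 0.835), the ubiquitin ligase gene Ubr4 (0 to 0.768), Atg2a, a lipid transfer protein of autophagy (0 to 0.737), and Plcg1, a phospholipase of receptor signalling (0 to 0.728). Lower were introns of Vps13a (0.927 to 0), Pik3c2a (0.670 to 0), Isyna1, which encodes inositol-3-phosphate synthase (0.571 to 0), Lemd3 of the inner nuclear membrane (0.529 to 0) and the SWI/SNF subunit gene Smarcd1 (0.493 to 0). Introns listed at 0 in wild type made up 9.52% of all higher calls, and introns at 0 in the knockout made up 28.8% of the lower calls.

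Splicing genes were mostly on the higher side in mouse HSC, as were genes at large, of which 3899 of 6639 had a higher intron and 891 a lower one. Apart from the kinases, the medians of the splicing lists lay inside the range of random lists. The SR proteins gave 4 higher and 1 lower after centring. Of 22 U2 snRNP and branch point factors, 16 were higher, 1 lower and 6 neither (13 higher and 2 lower after centring), with Sf3a1 at 0.00766 and 0.252 (log2 change 3.89) and Puf60 at 0.0407 and 0.479 (3.27). Of 23 hnRNP genes, 16 were higher, 2 lower and 6 neither (7 higher and 4 lower after centring), with Ptbp3 at 0.0718 and 0.733. Of 43 other spliceosome subunits, 37 were higher and 7 lower (26 and 10 after centring), with Snrnp200, the helicase that unwinds U4/U6, going from 0 to 0.274 and Cwc22 from 0.149 to 0. The 7 minor spliceosome genes gave 3 higher and 0 lower (2 and 0 after centring), with Zrsr2 at 0.0428 and 0.122. Of 16 nonsense-mediated decay factors, 13 were higher and 1 lower (10 and 4 after centring); the kinase gene Smg1 went from 0.303 to 0. The 10 splicing factor kinases gave 6 higher and 3 lower, but 3 higher and 4 lower after centring, and their median of 0.40 lay at the 2.10 percentile of matched random lists, but inside the central 95% under each alternative (2.62 to 8.99).

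Among chromatin genes, 44 of 52 chromatin modifiers were higher and 16 lower (36 and 20 after centring), and 13 counted in both directions. An intron of Asxl1, a Polycomb-associated gene often mutated in clonal blood disorders, was at 0.719 in wild type and 0.0190 in the knockout, while Bptf went from 0 to 0.238. Of 8 genes of the DNA methylation machinery, 4 were higher and 2 lower (4 and 3 after centring), the knocked-out gene among the higher ones, with the maintenance methyltransferase gene Dnmt1 at 0.0214 and 0.228. Of 30 DNA repair genes, 21 were higher and 1 lower (15 and 2 after centring), with Atr (0 to 0.269) and Mdc1 (0 to 0.268) among them. The p53 list gave 7 higher and 1 lower of 12 (5 and 1 after centring), with Trp53 itself at 0.0171 and 0.167. Cell cycle regulators gave 15 higher, 4 lower and 16 neither of 32 (11 higher and 4 lower after centring). Top2a was at 0.0249 and 0.273 and Rb1 at 0.0376 and 0.291. Before any alternative, the medians of all these lists lay inside the range of random lists. Chromatin modifiers were at the 57.6 percentile, DNA methylation genes at 64.5 and DNA repair genes at 92.7. The p53 list was at 76.45 and cell cycle regulators at 5.11.

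Of 18 blood stem cell regulators, 13 were higher and 4 lower (7 and 4 after centring), with Cd34 at 0.0301 and 0.253 and the Polycomb gene Bmi1 going from 0 to 0.171. Erythroid and megakaryocytic markers had a median of 1.34, at the 98.8 percentile (87.7 and 61.1 under alternatives), on 6 genes, of which 3 were higher and 1 lower (1 and 2 after centring); the transferrin receptor gene Tfrc was at 0.0736 and 0.539. Of 7 myeloid markers 3 were higher and 0 lower (3 and 2 after centring), with Csf3r at 0.0353 and 0.220, but the list median was 0.16, at the 8.5 percentile, and -0.12 with the highest-score intron of each gene. Of 3 lymphoid markers 2 were higher and 0 lower (1 and 2 after centring), with Notch1 at 0.145 and 0.428, and both stromal genes measured were past the rule in neither direction (1 lower after centring). The 3 pluripotency genes gave 2 higher (1 after centring), with Klf4 at 0.286 and 0.840. Of 11 retinoic acid response genes, 6 were higher and 2 lower (6 and 3 after centring). No germ layer regulator was measured. Of 57 cytosolic ribosomal protein genes, 8 were higher, 0 lower and 49 neither, with Rpl21 at 0.348 and 0.935, and the list lay at the 0.020 percentile. After centring, 0 were higher and 2 lower. Respiratory chain genes gave 24 higher and 2 lower of 73 (9 and 3 after centring), with a median of 0.79.

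In mouse ESC after 24 h of ATRA, scores went both ways. Of 21039 introns kept, 4107 were higher in the knockout, 4829 lower and 12103 neither, and the median log2 change was -0.62. Among 43 other spliceosome subunits, 34 were higher and 22 lower (37 and 20 after centring), with Snrnp200 at 0.00242 and 0.776 and Dhx8 at 0.00748 and 0.466, and the median of 0.24 lay at the 99.0 percentile of matched random lists. Introns of pluripotency genes were among those listed at 0 in the knockout, as for Utf1 (0.161 to 0) and Lefty1 (0.139 to 0). The pluripotency list as a whole gave 6 higher and 7 lower, at a median of 0.44 against -0.60 for all genes. The knockout column listed 62.9% of all introns at exactly 0 against 3.73% in wild type, and 85.0% of the lower calls were introns at 0 there. Without introns at 0, the median was 1.06 and 84.8% of the calls were higher.

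**Figure D2:**
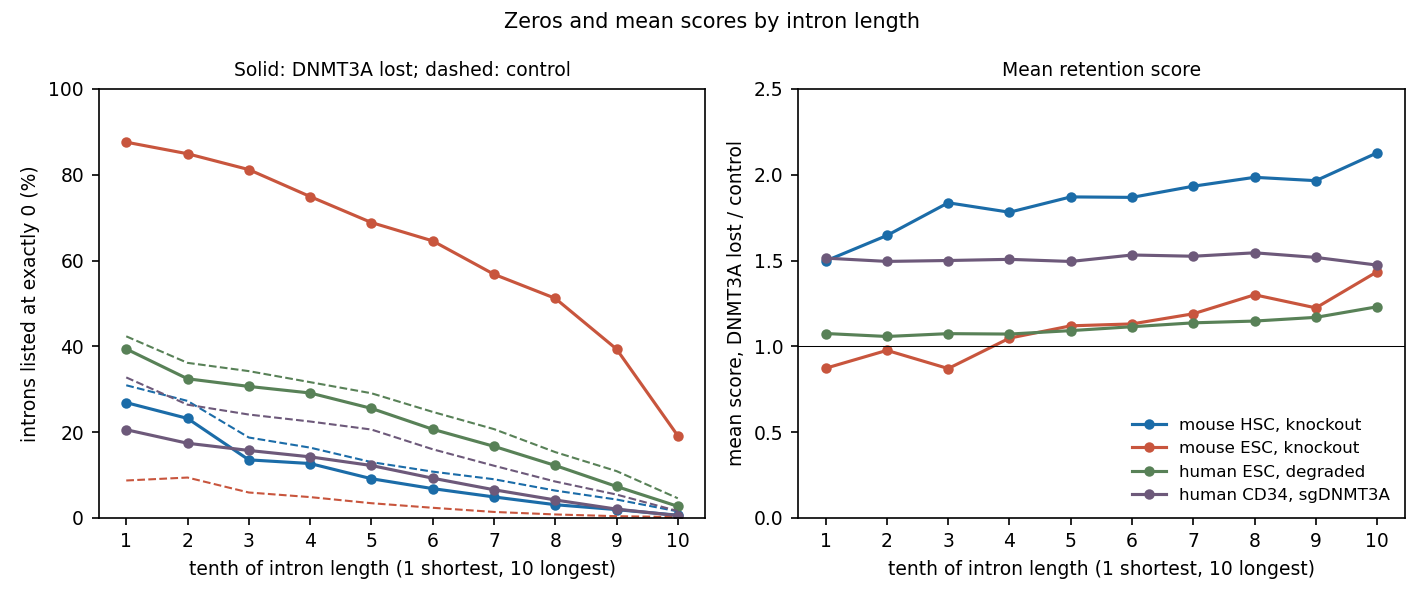
Share of introns listed at exactly 0 (left, percent) and ratio of the mean score without DNMT3A to that of the control (right), by class of intron length, 10 classes of equal size from shortest to longest (horizontal axis), for the 4 comparisons; dashed lines on the left are controls. In knockout mouse ESC the share at 0 goes from 87.6% in the shortest class to 19.1% in the longest, and the ratio of means from 0.872 to 1.43.

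The direction in mouse ESC followed intron length. With introns cut into 10 classes of equal size by length, the ratio of mean scores, knockout over wild type, was 0.872 in the shortest class and 1.43 in the longest. Over all 39277 listed introns it was 1.05. The median log2 change was 0.48 among introns of at least 1000 bases, a setting chosen after the data were seen.

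The targeted gene, Dnmt3a, lies on the plus strand of chromosome 12 in mm10, and 12 of the 22 introns of its annotated transcript were listed, all in the coding region. Intron 14, at 3899700 to 3899863, had a score of 0.00678 in wild type and 2.05 in the knockout. Intron 16, at 3900362 to 3901548, was at 0.00438 and 0.411. Intron 17, at 3901695 to 3902380, was at 0.0386 and 0.753, and intron 19, at 3902815 to 3904139, at 0.0116 and 0.325. The other 8 listed introns, on both sides of these, were at 0 in the knockout and at 0.00154 to 0.0201 in wild type.

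**Figure D3:**
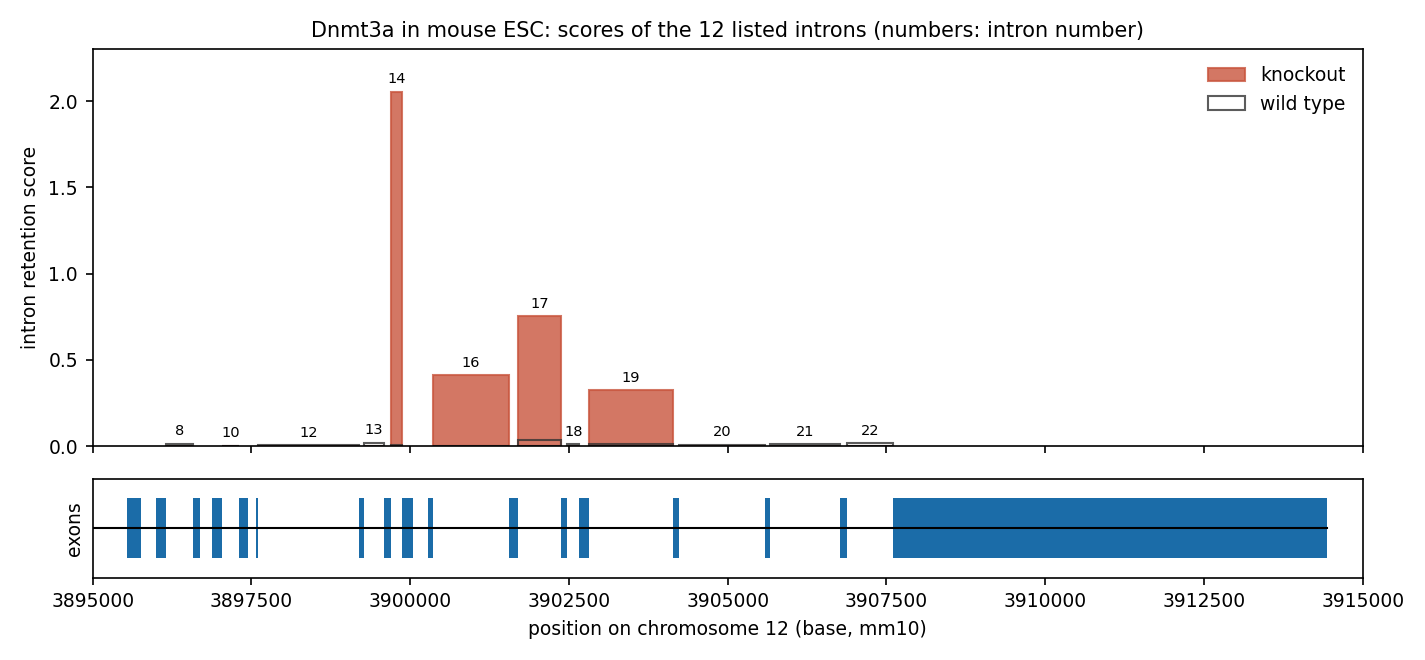
Retention scores (vertical axis, no unit) of the 12 listed Dnmt3a introns in mouse ESC, drawn to scale along chromosome 12 of mm10 (horizontal axis, base), knockout filled and wild type outlined, with the exons of the annotated transcript below. Introns 14, 16, 17 and 19 reach 2.05, 0.411, 0.753 and 0.325 in the knockout, and the rest are listed at 0 there.

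The largest increases in mouse ESC included introns of Kirrel (0 to 0.986), Hook1 (0 to 0.795), the complex I subunit gene Ndufs1 (0.00118 to 0.885), Fat1 (0.00117 to 0.833), Trp53bp1 of DNA break repair (0.00118 to 0.768) and the histone chaperone gene Chaf1a (0.00213 to 0.833). The largest decreases all ended at 0, from 0.971 in the RNA methyltransferase gene Nsun5, 0.955 in Pidd1, 0.940 in Ccdc22, 0.911 in Gga3 and 0.897 in Sharpin.

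The gene lists in mouse ESC were split in most cases, as were genes at large, of which 2438 of 6161 had a higher intron and 2674 a lower one. Of 9 genes of the DNA methylation machinery, 7 were higher and 3 lower, the knocked-out gene among the higher ones, with Dnmt1 at 0.0103 and 0.877 (intron 26 of 38) and Tet1 at 0.238 and 0. Of 22 U2 snRNP and branch point factors, 15 were higher and 14 lower (15 and 13 after centring), with Sf3a1 at 0.00866 and 0.461 and U2af1l4 at 0.476 and 0. SR proteins gave 5 higher and 5 lower of 12 (5 and 4 after centring), with Srsf6 at 0.00541 and 0.179 and Srsf4 at 0.123 and 0. Of 23 hnRNP genes, 10 were higher and 13 lower (12 and 11 after centring), and the lower ones included Hnrnph3 (0.440 to 0) and Hnrnpdl (0.286 to 0). Splicing factor kinases gave 8 higher and 6 lower of 11, with Clk1 at 0.487 and 0 and Cdk11b at 0.0204 and 0.963. The 6 minor spliceosome genes gave 1 higher and 2 lower, with Snrnp25 at 0.0744 and 0.424. Of 14 nonsense-mediated decay factors, 4 were higher and 11 lower, at the 22.4 percentile, inside the range of random lists, with the helicase gene Upf1 at 0.289 and 0.

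For stem cell and lineage lists in mouse ESC, 21 pluripotency factors gave 6 higher, 7 lower and 10 neither, at a median of 0.44 and the 95.1 percentile. Of 13 retinoic acid response genes, 5 were higher and 5 lower, with the receptor gene Rxrb going from 0.211 to 0. Of the 2 germ layer regulators measured, 1 was lower. The 6 blood stem cell regulators gave 1 higher and 2 lower. The 3 erythroid and megakaryocytic genes gave 2 higher and 2 lower, with the mitochondrial iron carrier gene Slc25a37 at 0.502 and 0.00568, and 2 of 3 lymphoid genes were lower (1 after centring). No myeloid marker was measured. Among 4 stromal and feeder cell genes 1 was higher, the fibronectin gene Fn1 at 0.00140 and 0.191.

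Of 37 DNA repair genes in mouse ESC, 20 were higher and 19 lower (22 and 19 after centring), with Fanca (0.368 to 0) and Xrcc1 (0.304 to 0) among the latter. Chromatin modifiers gave 35 higher and 30 lower of 51 (37 and 29 after centring), and the H3K79 methyltransferase gene Dot1l went from 0.547 to 0. The 19 p53 pathway genes gave 5 higher and 5 lower (6 and 5 after centring), with Mdm4 at 0.0140 and 0.329. Cell cycle regulators gave 19 higher and 11 lower of 34, with Aurkb at 0.223 and 0 and Bub1 at 0.00243 and 0.202. Of 64 cytosolic ribosomal protein genes, 7 were higher, 9 lower and 49 neither (11 higher and 8 lower after centring), at a median of -0.18 against -0.60 for all genes and the 97.8 percentile. The median changed sign, at the 70.4 and 24.2 percentiles, with the highest-score intron and with a mean score of at least 0.05. Rpl23a went from 0.316 to 0. Respiratory chain genes gave 8 higher and 18 lower of 58 (9 and 17 after centring).

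In human ESC after 12 h of ATRA, few introns moved when DNMT3A was degraded. Of 24500 introns kept, 687 were higher, 451 lower and 23362 neither, with a median log2 change of 0.12. An intron of CDKN1A, which encodes the cell cycle inhibitor p21, went from 0.0106 to 0.102 (log2 change 2.45), and the Fanconi anemia gene FANCE from 0.132 to 0.394 (1.51). None of 17 U2 snRNP and branch point factors, 11 SR proteins, 17 hnRNP genes, 13 pluripotency factors, 32 cytosolic ribosomal protein genes or 27 respiratory chain genes had an intron past the rule. The ratio of mean scores was 1.09, and no list lay outside the central 95% of its random lists. DNMT3A was looked for in both human comparisons, and no intron of it was among those read.

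The largest increases in human ESC were introns listed at 0 in wild type, in SIPA1L3 (0.405 after degradation), FAM160B1 (0.336), VWCE (0.321), the laminin gene LAMA5 (0.278) and the sorting nexin gene SNX27 (0.259). The largest decreases ended at 0, from 0.237 in the tyrosine kinase gene FES, 0.234 in CCDC74A, 0.224 in UNC13D and 0.204 in MAPK8IP3. Of the higher introns 32.5% were listed at 0 in wild type, and of the lower ones 34.1% were at 0 after degradation.

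Of all 6989 genes kept in human ESC, 522 had a higher intron and 362 a lower one. Chromatin modifiers, the largest list measured, gave 6 higher and 7 lower of 47, at the 72.3 percentile. Among them were the H3K4 methyltransferase gene KMT2B (0 to 0.191), KMT2E (0 to 0.170) and the deacetylase gene HDAC6 (0.171 to 0.0290). Other spliceosome subunits gave 3 higher and 1 lower of 35, with RBM10 at 0.0350 and 0.162, PRPF40B at 0.0420 and 0.182, and SYF2 at 0.0866 and 0.0360. Of 39 DNA repair genes 3 were higher and 1 lower, with EME2 at 0.137 and 0.408 and RECQL4 at 0.152 and 0.346. Splicing factor kinases gave 2 higher of 8, CLK4 (0 to 0.128) and DYRK1B (0.0512 to 0.124). The nonsense-mediated decay list gave 1 of 14, SMG1 at 0.0228 and 0.154. The DNA methylation list of 9 gave MBD4 higher (0.0341 to 0.0934) and MBD1 lower (0.176 to 0.0825). The retinoic acid list gave 1 higher of 10, and CDKN1A was the only higher gene among 11 of the p53 list. Of 31 cell cycle regulators 2 were higher, with CDT1 at 0.0409 and 0.0924, or 1 after centring. Of 4 blood stem cell regulators 1 was higher, and of 4 lymphoid genes 1 was lower. The 4 minor spliceosome, 4 erythroid and megakaryocytic, 5 stromal and 2 germ layer genes measured had no intron past the rule, and no myeloid marker was measured.

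In human CD34 cells, the sgDNMT3A group had higher scores at most introns, as the knockout had in mouse HSC. Of 35822 introns kept, 2846 were higher, 277 lower and 32699 neither, and the median log2 change was 0.50. AZU1, which encodes the neutrophil granule protein azurocidin, went from 0.228 to 0.869 (log2 change 1.88), the helicase gene DDX23 from 0.0609 to 0.257 (1.91), and the replication gene MCM4 from 0.137 to 0.420 (1.55). Against the direction of the rest, an intron of the DNA damage kinase gene ATM went from 0.935 to 0.261 (-1.80). Centring left 1208 higher and 468 lower, or 72.1% higher instead of 91.1%, again with the difference taken on the scores as listed.

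The largest changes in CD34 cells were introns listed at 0 in 1 of the groups. Higher with sgDNMT3A were introns of the polycystin gene PKD1 (0.348), the Mediator subunit gene MED25 (0.277), RAB13 (0.232), PORCN, which acylates WNT proteins (0.228), and the H3K27 demethylase gene KDM6B (0.221). Introns of RAB11FIP4 (0.320), CUL7 (0.237), UBR4 (0.232), the cyclin gene CCNE2 (0.176) and ABCA7 (0.166) in the Cas9 group were at 0 with sgDNMT3A.

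Splicing lists in CD34 cells leaned to the higher side as genes at large did, of which 1788 of 7607 had a higher intron and 251 a lower one, and none lay outside the range of random lists. Other spliceosome subunits gave 8 higher and 0 lower of 38 (5 and 0 after centring), with PRPF8, the core U5 protein, at 0.0530 and 0.185. hnRNP genes gave 4 higher of 19 (0 after centring), with HNRNPA3 at 0.0937 and 0.247 and PTBP1 at 0.0560 and 0.152, and had the largest median of the splicing lists, 0.65, at the 97.4 percentile. Of 19 U2 snRNP and branch point factors 4 were higher and 1 lower (2 and 1 after centring), with U2AF1 at 0.0305 and 0.0934. SR proteins gave 2 higher of 11 (0 after centring), SRSF11 and SRSF5, at 0.0893 and 0.190 and at 0.0714 and 0.153. Splicing factor kinases gave 3 higher of 9, CLK2, CLK3 and CLK4, the first at 0.0435 and 0.169, and 1 higher and 1 lower after centring. The 17 nonsense-mediated decay factors gave 3 higher (1 after centring), with UPF1 at 0.0467 and 0.142. None of the 4 minor spliceosome genes was past the rule.

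Chromatin modifiers in CD34 cells gave 17 higher and 1 lower of 52, but 7 higher and 8 lower after centring, with CHD8 going from 0 to 0.164. DNA repair genes gave 12 higher and 2 lower of 37 (7 and 4 after centring), with RAD51D at 0.0322 and 0.141. Medians of the chromatin and repair lists, 0.45 and 0.42, lay below the 0.50 of all genes. Before any alternative they were at the 6.78 and 5.0 percentiles, inside the range of random lists. Of 8 DNA methylation genes 2 were higher (1 after centring), with DNMT3B at 0.0355 and 0.0930. Of 18 blood stem cell regulators 1 was higher, LYL1 at 0.0275 and 0.0973. The 9 myeloid markers gave 2 higher, AZU1 and CSF1R, and 1 lower (1 and 1 after centring), and the 5 erythroid and megakaryocytic genes 1 lower, GP9 at 0.118 and 0.0242. Of 11 lymphoid genes 2 were higher, LCK at 0.0186 and 0.0821 and NOTCH1 at 0.0212 and 0.0878. The p53 list gave 2 higher of 15 (1 after centring), with XPC at 0.0190 and 0.173, and cell cycle regulators 4 higher and 1 lower of 40 (2 and 1 after centring). Of 7 retinoic acid response genes 2 were higher, with NCOA2 at 0.0950 and 0.219, or 1 higher and 1 lower after centring, and of 4 pluripotency genes 1 was higher, DPPA4 (0 after centring). The 3 stromal genes were not past the rule, and no germ layer gene was measured. Of 32 ribosomal protein genes 1 was higher (0 after centring), at a list median of 0.35 against 0.50 for all genes, and respiratory chain genes gave 6 higher of 48 (4 after centring), with NDUFS8 at 0.0275 and 0.133.

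**Figure D4:**
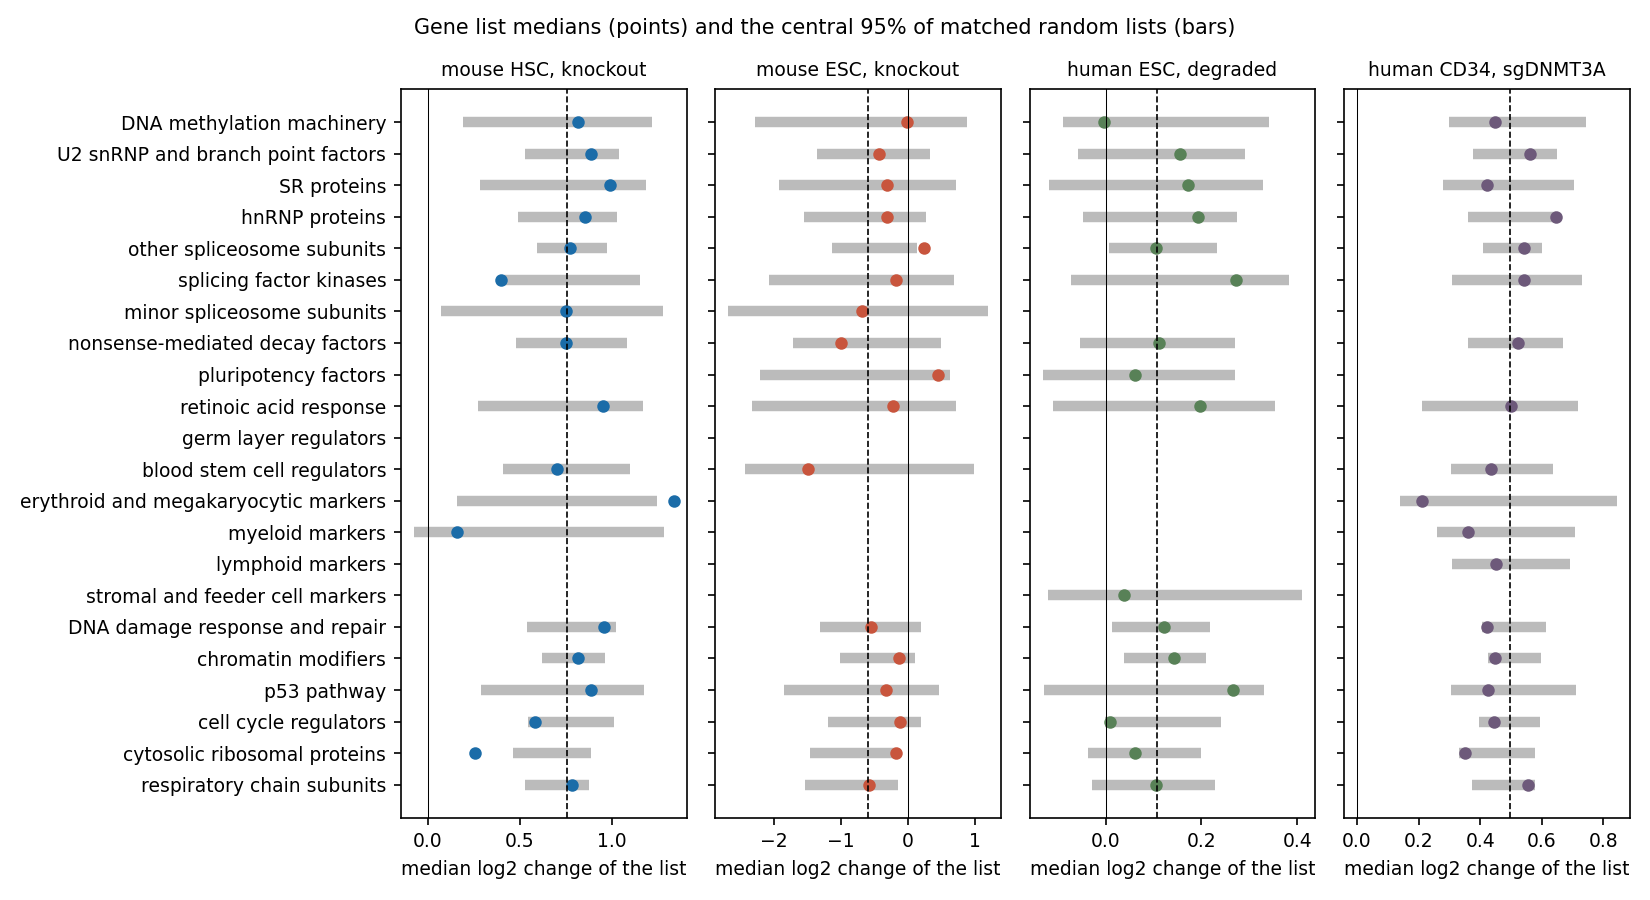
Median log2 change of each gene list (points, horizontal axis) in the 4 comparisons, beside the central 95% of medians of matched random lists (grey bars); the dashed line is the median of all genes, and lists with fewer than 5 measured genes are left out. Cytosolic ribosomal proteins in mouse HSC, at 0.26, lie left of the grey bar, and other spliceosome subunits in mouse ESC, at 0.24, lie right of it.

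Across the 4 comparisons, 69 list medians had a percentile, and 5 lay outside the central 95%, where chance gives 3.45. In this setting all 5 were in mouse cells. With the highest-score intron in place of the gene's mean, the mouse HSC ribosomal proteins stayed at the 0.010 percentile, the splicing factor kinases were at 8.99 and the erythroid and megakaryocytic markers at 87.7. In mouse ESC the spliceosome subunits were then at the 97.3 percentile and the ribosomal proteins at 70.4. Other lists moved outside the range in that setting, DNA repair genes (99.4) and cell cycle regulators (0.63) in mouse HSC and chromatin modifiers (0.75) in human CD34 cells. With a pseudocount of 0.05, cell cycle regulators (0.51) and myeloid markers (2.2) in mouse HSC and ribosomal proteins (2.06) in CD34 cells were outside it. With a mean score of at least 0.05, DNA methylation genes (98.7), splicing factor kinases (97.7) and cell cycle regulators (99.6) in mouse ESC and U2 snRNP factors (97.6) in CD34 cells were. Only the mouse HSC ribosomal proteins were outside the range in every setting.

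The comparison of cell systems asked whether the same introns or genes moved. Between the mouse systems, introns of Polrmt (intron 16 of 20), the mitochondrial RNA polymerase gene, and Apba3 (intron 6 of 10) were lower in both, at 0.0779 to 0 and 0.451 to 0.147 in HSC and at 0.169 to 0 and 0.408 to 0 in ESC. Intron 2 of 8 of Slc25a20, the mitochondrial carnitine carrier gene, was higher in both, at 0.0203 to 0.113 and 0.00878 to 0.204. Among 11678 introns kept in both mouse tables, 639 were higher in both, where independent lists would share 657.2, or 480.5 when matched on score level, so the side depended on the matching. Lower in both were 171, where independent lists would share 80.5, or 90.3 when matched. The matching was on score level and not on intron length. Among 17789 introns kept in both human tables, 92 were higher in both against 48.7, or 65.4 when matched, and 8 were lower in both against 2.02, or 2.25 when matched. The Spearman correlation of log2 changes, across introns that are not independent replicates, was 0.0913 in mouse and 0.0186 in human.

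Across species, genes were matched by symbol. After matching on the number of introns kept, mouse and human blood cells shared 884 higher genes against 868.6 and 59 lower genes against 39.4, and mouse and human ESC shared 117 higher genes against 122.7 and 158 lower genes against 126.7. Mouse HSC and human ESC shared 198 higher genes against 200.4 and 88 lower genes against 58.1, and mouse ESC and human CD34 cells 510 higher against 562.4 and 110 lower against 87.1. Without matching, the numbers for higher genes in these last pairs were 187.3 and 507.6, on the other side of those observed. Of 3148 genes kept in all 4 tables, 462 were higher in at least 3 comparisons, where independence gives 529.7. Lower in at least 3 were 93, where it gives 53.1. Both expected numbers were summed within classes of the number of kept introns and did not take account of intron length. Genes higher in 3 comparisons included Ago1, of the Argonaute family, in mouse HSC (0 to 0.304), mouse ESC (0.0155 to 0.936) and human CD34 cells (0 to 0.0767), the lipoamide dehydrogenase gene Dld (0.0162 to 0.139, 0.0204 to 0.553 and 0.0346 to 0.0950) and Herc1 (0.00719 to 0.192, 0 to 0.493 and 0.0424 to 0.103). Genes lower in 3 included Telo2, a chaperone of PI3K-like kinases, in the same systems (0.373 to 0, 0.409 to 0 and 0.114 to 0.0347), Hdac6 in mouse HSC, mouse ESC and human ESC (0.149 to 0, 0.203 to 0 and 0.171 to 0.0290), and Gadd45g there (0.108 to 0.0450, 0.189 to 0 and 0.0665 to 0). The introns past the rule in a gene were not always the same intron.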

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

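No paired analysis was possible because the columns analysed are group averages, which carry no replicate number, and for the same reason no sample was left out in turn. Read depth is unknown, so scores resting on few reads could not be set apart, and an average of 0 can come from few reads as well as from complete splicing. Counting each result once under each alternative, those on the calls, overlaps and baseline shares stayed the same 87 times, moved 101 times and reversed 4 times; the others stayed the same 321 times, moved 512 times and reversed 2 times. Among 314 named introns, a pseudocount of 0.001 moved 204 and a pseudocount of 0.05 moved 252, and none reversed. The direction of the median change in mouse HSC, human ESC and human CD34 cells held under every alternative that can change it, and that in mouse ESC did not. Centring sets the median to 0, and the fold and difference limits leave it as it is.

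In the order mouse HSC, mouse ESC, human ESC and human CD34 cells, the median log2 change was 1.002, -0.81, 0.16 and 0.64 with a pseudocount of 0.001 and 0.44, -0.31, 0.059 and 0.26 with a pseudocount of 0.05, which also left 418 higher and 284 lower introns in human ESC and 1410 and 172 in CD34 cells. With no filter on low scores it was 0.58, -0.53, 0.011 and 0.24. With a mean score of at least 0.05 it was 0.88, 0.50, 0.11 and 0.57, with 2514 lower in mouse ESC and 300 in human ESC. Without scores of exactly 0 it was 0.77 in mouse HSC, 1.06 in mouse ESC and 0.49 in CD34 cells, with 725 lower in mouse ESC and 297 in human ESC. With 1 intron per gene it was 0.88, 0.32, 0.097 and 0.53, with 2508 higher and 224 lower, 2042 and 1529, 195 and 133, and 783 and 66. Among introns of at least 1000 bases it was 0.86, 0.48, 0.14 and 0.48, with 4351 and 99, 2310 and 1227, 61 and 21, and 603 and 4. With the gene-level score it was 0.76, -0.054, 0.10 and 0.46, with 1135 and 73, 453 and 905, 23 and 13, and 148 and 17; fewer units were counted in these last 3 settings. In mouse ESC the median thus reversed with the mean score of at least 0.05, without zeros, with 1 intron per gene and among longer introns. Leaving out zeros removes the introns that made up 85.0% of its lower calls; for the other 3 settings the cause was not tested.

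A difference limit of 0.1 left 5465 higher and 587 lower introns in mouse HSC, 2390 and 2295 in mouse ESC, 230 and 161 in human ESC, and 1387 and 104 in CD34 cells. A limit of 0.02 gave 14359 and 2054 in mouse HSC, 9863 lower in mouse ESC, 1835 and 1226 in human ESC, and 5400 and 703 in CD34 cells. A fold limit of 1.5 gave 1066 and 702 in human ESC and 5502 and 434 in CD34 cells. Centring gave 4429 and 1844 in mouse HSC and 1208 and 468 in CD34 cells. With the difference limit of 0.1, the overlap over that of independent lists, without matching, was 3.56 instead of 2.12 for lower introns of the mouse systems, 2.45 instead of 1.62 for lower genes of mouse and human ESC and 2.84 instead of 1.89 for higher introns of the human systems. The share of introns with a score of at least 0.05 was 27.5% and 43.4% in wild-type and knockout mouse HSC, 18.1% and 16.5% in mouse ESC, 8.30% and 9.18% in human ESC without and with degradation, and 15.5% and 22.2% in CD34 cells with Cas9 and sgDNMT3A. Among introns in both tables of a species the share at 0.1 or more was 13.1% and 25.9%, 6.73% and 8.74%, 3.56% and 3.89%, and 7.28% and 11.7% in the same order. Cytosolic ribosomal proteins in mouse ESC reversed to a median of 0.040 with the highest-score intron of each gene and to 0.0067 with a mean score of at least 0.05; the cause was not tested. Only lists outside the random range count as reversed here; among all lists, with at least 5 genes measured under the alternative, the median changed sign under at least 1 alternative in 12 of 17 lists in mouse ESC, 1 of 18 in mouse HSC, 2 of 16 in human ESC and 0 of 18 in CD34 cells.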

Other observations

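In the patterns weighed below, the tests for too few reads and for reads added evenly were written before they were run. Those for lower retention, depth alone and a common factor were chosen after the result was seen. A range in brackets after a ratio is the central 95% of 1000 resamplings of genes. It describes spread across genes within the averaged columns and holds no spread between samples.

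Among the listed introns of a gene, the last had the highest mean score in every control group. First and last refer here to listed introns, which need not be the first and last of the transcript. In genes with at least 5 listed introns, the mean score of the first, internal and last listed introns was 0.0398, 0.0520 and 0.0663 in wild-type mouse HSC and 0.0280, 0.0294 and 0.0427 in Cas9-treated human CD34 cells. In wild-type mouse ESC the last introns had a mean of 0.0464 against 0.0305 for internal ones, and in wild-type human ESC 0.0252 against 0.0156. Last introns were also shorter, with a median of 864 bases in mouse HSC against 2276.5 for first introns. Without DNMT3A the mean of first, internal and last introns was 1.72, 1.85 and 1.68 times that of the control in mouse HSC and 1.45, 1.53 and 1.49 times in CD34 cells, so the higher means were not tied to last introns. In mouse ESC the same values were 1.28, 1.28 and 0.885.

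Genes lower in all 4 comparisons numbered 14, where independence gives 2.63, and genes higher in all 4 numbered 53, where it gives 55.0. These expected numbers did not take account of intron length. Lower introns of at least 1000 bases numbered 99 of 1138 in mouse HSC and 1227 of 4829 in mouse ESC. In human ESC and CD34 cells they numbered 21 of 451 and 4 of 277. Genes with several short introns could be lower together for that reason, which was not tested. The mitochondrial RNA polymerase gene Polrmt was lower through short introns in 3 systems, of 94 bases in both mouse tables and 95 bases in human CD34 cells, where the score went from 0.0602 to 0. APBA3 was lower in human ESC as well, from 0.391 to 0.166. SLC25A20 was higher in CD34 cells, from 0.0557 to 0.160.

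The lower scores at most introns of knockout mouse ESC may come from too few reads in those libraries, but the test for this cannot decide. The share at 0 fell by 68.5 percentage points from the shortest to the longest introns. It also fell in control groups, from 42.3% to 4.56% in wild-type human ESC and from 32.7% to 1.57% in Cas9-treated CD34 cells. In wild-type mouse ESC it fell from 8.71% to 0.178%. An effect on short introns would give such a fall as well. The test for lower retention at most introns took it to lower the mean as well, and the ratio of means was 1.05 (1.008 to 1.099 by resampling genes). It cannot decide, because a minority of high scores can hold up the mean. Scores above 1 numbered 30 in wild type and 170 in the knockout, while the median score went from 0.0123 to 0. Dnmt3a loss and library are the same split of the samples here, so an effect of DNMT3A on short introns stays open.

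Scores were higher in knockout mouse HSC, with a ratio of means of 1.79 (1.77 to 1.82 by resampling genes). The test took read depth alone to leave the mean unchanged, which was not checked. A ratio can be large on few junction reads, and scores above 1 numbered 23 in wild type and 217 in the knockout. Read depth therefore stays open. Reads added evenly along each gene, as unspliced RNA or genomic DNA would add them, are a candidate explanation by the test within genes. The mean difference in the shortest over the longest introns of the same genes was 1.04 (0.876 to 1.22, 1686 genes). A common factor for every intron would give the same ratio at all lengths, and the longest introns had 1.42 times the ratio of the shortest (1.351 to 1.495). In simulated data made from the wild-type column, reads added evenly gave 2.04 there, a value that depends on the amount added. Over all listed introns, the mean score went from 0.0925 to 0.139 in the shortest of 10 length classes. In the longest it went from 0.0247 to 0.0525, a smaller rise. These 2 classes do not hold the same genes, and the amount added may differ between genes, so this contrast cannot decide. Whether even addition accounts for the whole change stays open. A rise in unspliced RNA through loss of DNMT3A and one through library preparation would look alike in these values.

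In human CD34 cells scores above 1 numbered 12 with Cas9 and 95 with sgDNMT3A, and read depth stays open here too. The ratio of means was 1.51 (1.497 to 1.522 by resampling genes). Within genes, the difference was 1.78 times as large in the shortest as in the longest introns (1.54 to 2.04, 2520 genes). In simulated data made from the Cas9 column, reads added evenly gave 0.998 there and a common factor of 1.5 gave 1.98. Reads added evenly alone would thus not give this value. A mixture was not tested, so they stay open as a part of the rise. A common factor for every intron is a candidate explanation, since the ratio in the longest introns was 0.973 times that in the shortest (0.943 to 1.004). Such a factor may come from splicing in these cells or from how junction reads were obtained, and loss of DNMT3A stays open.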
